A study of Homo sapiens with 2 samples.

How the data were processed

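MicroRNA (miRNA) levels were measured by array in 2 samples of Hep3B2.1-7, an established human hepatocellular carcinoma cell line. One sample was transfected with an anti-miR against miR-191, an antisense oligonucleotide that binds and blocks the mature miRNA, and the other with a negative-control anti-miR. Per the labels' protocols, transfection used Oligofectamine, and 15 µg of total RNA per sample was labelled by ligating a Cy-dye linker. The control RNA carried Cy3 and the anti-miR-191 RNA carried Cy5. Per the series design text, each array was hybridised in dual-channel format with an unrelated sample in the other channel, and channels were not meant to be compared within an array. Each group therefore has n = 1, and dye, array and treatment cannot be told apart.

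The deposited table gives 1 log2 signal per probe and sample for 719 probes. Its scale was read from the values: both columns share a lowest value of 5.64, which is log2 of a signal of 50, and no value is missing. The deposited signals therefore carry a floor, with 540 probes (75.1%) at the floor in the control and 539 (75.0%) in the anti-miR-191 sample. The scanner, background correction, floor rule and normalization between arrays are not given in the sources used here. Over the 168 probes above the floor on both arrays the median log2 difference was -0.01, so the deposited scaling was kept, by a rule that allowed up to 0.1 before re-centring.

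Of the 719 probes, 666 carry a human mature miRNA name, which gave 665 names after the 2 probes of 1 name were averaged. The other 53 probes are small RNA controls or sequences with no human mature miRNA name, and are not named here apart from the controls. Names are those of the array design and some are old (miR-122a, miR-128a). No genome build is given, so no coordinates are printed. Neighbouring miRNA genes (within 10000 bp) were found with a RefSeq gene table, which matched 146 of the 156 miRNAs above the floor on both arrays.

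From the deposited values, the difference log2(anti-miR-191) minus log2(control) was computed per miRNA. A miRNA was called measured when above the floor, and a difference with 1 side at the floor is given as a bound ("at least N-fold"). With 1 sample per group there is no test, standard error or p-value, and each difference compares 2 samples and not 2 conditions. The array number limits the precision. The spread of differences over the 156 miRNAs measured on both arrays describes how far a single miRNA stands apart.

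The design, the alternatives, 18 miRNA lists and the rule for named miRNAs were fixed before the data were examined. The rule takes miR-191, miR-425 and their star strands; up to 10 miRNAs per direction with at least a 2-fold difference; up to 5 per direction with a bound of at least 2-fold; the 10 brightest in the control; and up to 4 members of each list with the largest difference. The lists hold families, genomic clusters, liver and liver-cancer miRNAs, and markers of blood, stromal and neuronal cells. For each list with at least 3 members measured on both arrays, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean signal in 5 bins. That percentile describes these 2 samples. On simulated differences for the 156 miRNAs, lists of 5 with no shift fell outside the central 95% in 3% of draws, those shifted by 0.3 in 31.5% and those shifted by 0.6 in 83.5%. For lists of 3 these shares were 7%, 17.5% and 61%, and for lists of 10 they were 2.5%, 53% and 99.5%. The simulated differences were drawn from a normal distribution with the same SD at every signal level. Each draw was placed among fewer than 10000 random lists. The simulated differences were also independent of each other, whereas members of a family or cluster may differ together. The shares therefore need not hold for the real lists.

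Alternatives were equal medians, quantile normalization, loess on signal (span 0.5), a floor at the 75th percentile, no floor, thresholds of 1.5-fold and 3-fold, and the brighter probe per name. A floor at a log2 signal of 8 and scaling to the small RNA controls were added after seeing the data. Without replicates, a median or difference was called moved when it changed by at least 0.1 on the log2 scale. Work used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.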

Results

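The data comprised miRNA array profiles of Hep3B2.1-7 cells transfected with anti-miR-191 (n = 1) or with a negative-control anti-miR (n = 1). No value below has a replicate error. Of 665 human miRNAs on the array, 167 lay above the signal floor of 50 in the control and 168 in the anti-miR-191 sample. Both samples measured 156 of them, 11 were above the floor in the control only, 12 in the anti-miR-191 sample only, and 486 in neither. The deposited log2 signals of the 156 shared miRNAs had a median of 8.52 in the control and 8.59 after anti-miR-191.

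The 10 brightest miRNAs of the control are given with their signals, which depend on each probe and do not rank the amounts of different miRNAs. They were miR-103 at a signal of 33776, miR-106a at 26058, miR-574-3p at 24009, miR-107 at 23969, miR-17-5p at 21204, miR-181a at 20853, miR-92a at 14980, let-7e at 14483, miR-23b at 13778 and miR-483-5p at 11115. Of the liver-enriched miRNAs, miR-192 (4995) and miR-194 (3049) gave clear signals. The probe for miR-122, the most abundant miRNA of normal hepatocytes and named miR-122a on this array, was at the floor in the control and at 51.6 after anti-miR-191.

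The first comparison asked whether the targeted miRNA was lower after its anti-miR. The miR-191 signal was 7613 in the control and 2620 after anti-miR-191, a log2 difference of -1.54, or 2.91-fold lower (34.4% of the control). miR-425, whose gene is next to that of miR-191 within the gene DALRD3, had signals of 1258 and 1354, a log2 difference of 0.11 (0.025 with loess). Its star strand miR-425* lay near the floor, with a difference of -0.05 (0.19 with loess), and miR-191* was at the floor in both samples.

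miR-191 had the lowest difference of the 156 miRNAs measured in both samples. The next lowest was -0.87, for miR-214. The 156 differences had an SD of 0.36, or 0.33 without miR-191. Among the 40 miRNAs nearest to miR-191 in signal, differences ranged from -0.66 to 0.66. The value of miR-191 ranged from -1.61 to -1.02 over the 4 scaling alternatives that move it, and it was the lowest of the measured miRNAs under each of them. Its -1.02 came from scaling to the small RNA controls. Because the control was read in Cy3 and the anti-miR-191 sample in Cy5, no comparison here separates treatment from dye.

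**Figure D1:**
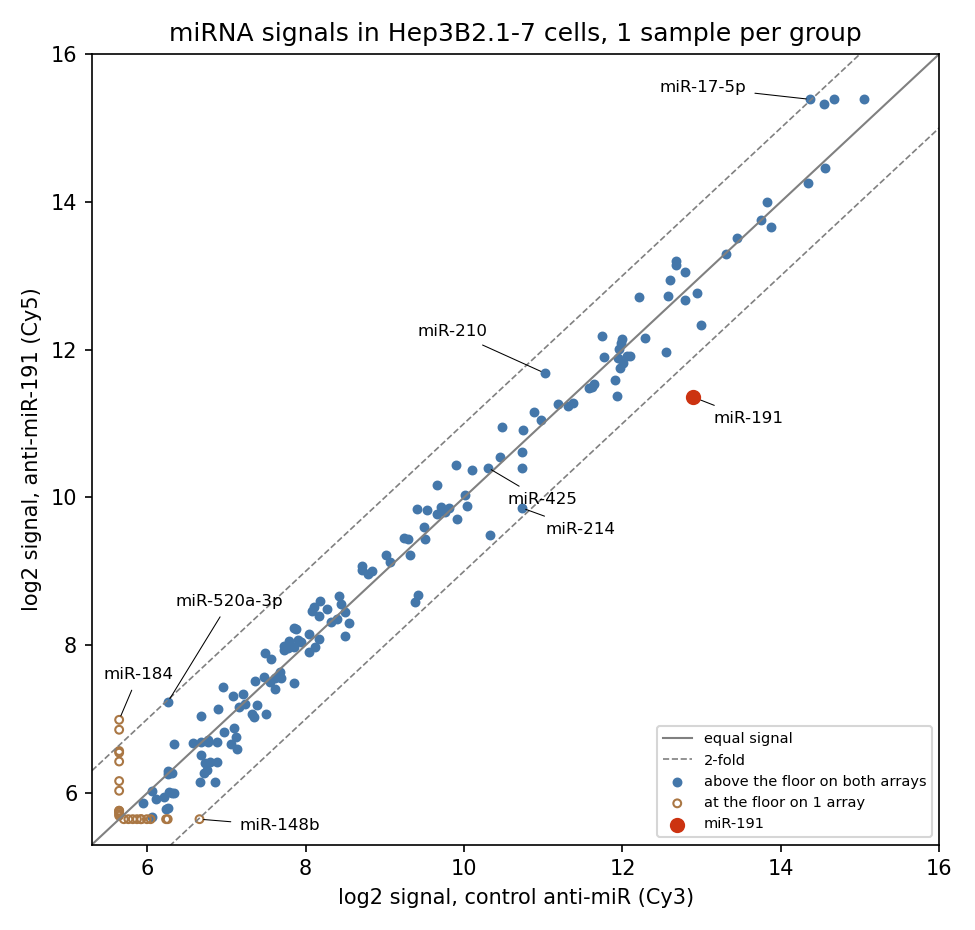
Log2 signal of each human miRNA in the control (x axis, Cy3) and after anti-miR-191 (y axis, Cy5), 1 sample each, with filled points for the 156 miRNAs above the floor in both and open points for those at the floor in 1. miR-191 lies at 12.89 and 11.36, below the dashed 2-fold line, while most other miRNAs lie near the line of equal signal.

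The second comparison covered all other miRNAs. The profiles were close: 136 of the 156 differences (87.2%) lay within 0.5 of 0 on the log2 scale, 77 were above 0 and 79 below. Across these miRNAs, which are not independent replicates, Pearson's r between the samples was 0.99 and Spearman's rho 0.99. miR-191 was the only miRNA measured in both samples that was at least 2-fold lower. miR-17-5p, the main strand of a growth-associated cluster, was the only such miRNA at least 2-fold higher, at 21204 in the control and 42816 after anti-miR-191 (log2 difference 1.01). That call ended with loess (0.99) and with quantile normalization (0.72), where miR-520a-3p passed in its place, at 1.13 and 1.07.

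At 1.5-fold, 5 miRNAs were higher and 8 lower. The higher ones were miR-17-5p, miR-520a-3p (0.97, from signals of 76.5 and 150), miR-107 (0.78), miR-106a (0.72) and miR-210, a hypoxia-inducible miRNA (0.66). The lower ones included miR-191, miR-214 (-0.87), miR-27b (-0.80), miR-27a (-0.74), miR-497 (-0.66) and miR-125a-5p (-0.59), with miR-766 (-0.83) and miR-933 (-0.71) outside the fixed naming rule and named after their values were seen. Quantile normalization kept 3 of the 5 higher and 6 of the 8 lower calls, losing miR-107 (0.46), miR-106a (0.22), miR-125a-5p (-0.41) and miR-933, while loess lost miR-933 alone and equal medians miR-125a-5p alone (-0.58). Scaling to the small RNA controls, described below, kept the 5 higher calls among 68 and left miR-191 as the only lower call, with miR-214 at -0.35, miR-27b at -0.28, miR-27a at -0.22 and miR-497 at -0.14.

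At the floor on 1 side, miR-184 was at least 2.54-fold higher after anti-miR-191 (floor against 127) and miR-223, a myeloid miRNA, at least 2.31-fold higher (floor against 116). miR-148b was at least 2.02-fold lower (101 against the floor), a bound that fell under 2-fold with quantile normalization (-0.89), loess (-0.74) and the small RNA scaling (-0.49). These 3 lie within a few-fold of the floor.

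Scaling to the 5 small RNA controls above the floor, whose differences ranged from -0.76 (RNU38B) to -0.19 (RNU6B) with a median of -0.52, moved the median of all miRNAs from -0.004 to 0.52. Every difference below is relative to the deposited scaling, and those between -0.52 and 0 change sign under the small RNA scaling. That scaling gave 9 miRNAs at least 2-fold higher and 1, miR-191, lower.

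The third comparison placed miRNA families and clusters among random lists. In the miR-17-92 and paralog clusters, 10 of 12 measured members were higher after anti-miR-191 and 2 lower, with a median of 0.20 at the 94.5 percentile of random lists (97.6 with quantile normalization, 89.2 with a floor at a log2 signal of 8). Its leading members were miR-17-5p and miR-106a, followed by miR-20b (0.38) and miR-93 (0.28, or 0.10 with quantile normalization). Of the let-7 family, 4 of 6 members measured in both samples were higher, led by let-7b (0.44) and let-7d (0.27, or 0.18 with loess), with let-7f at -0.32 (-0.052 with loess). A further 2 members were above the floor in 1 sample only and are not in this count. The let-7 median of 0.17 lay at the 88.8 percentile and was 0.076 with quantile normalization.

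miRNAs reported higher in liver cancer had the highest percentile of the 10 lists that have a percentile. Of 17 measured members 13 were higher and 4 lower, with a median of 0.25 at the 99.3 percentile of random lists, and none reached 2-fold. miR-210 (0.66), miR-222 (0.52), miR-221 (0.51) and miR-501-3p (0.48) led it. The clustered pair miR-221 and miR-222 is known to target the cell-cycle inhibitor p27. This list shares 4 of its 17 measured members with the miR-17-92 list. Its percentile was 96.4 with loess, inside the central 95% of random lists, where its median was 0.14.

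The miR-15/16 family, known for restraining the cell cycle, had the lowest percentile of these 10 lists. Of 4 members measured in both samples 3 were lower: miR-497 (-0.66), miR-16 (-0.32) and miR-15b (-0.32, or -0.12 with quantile normalization), while miR-503 was at 0.09. A further 1 was above the floor in 1 sample only, and 2 were in neither. The median of -0.32 lay at the 1.99 percentile, and it turned to 0.20 under the small RNA scaling, which shifts all lists alike and left the percentile at 1.98. With quantile normalization the median was -0.20 and the percentile 5.3. With percentiles for 10 lists, values outside the central 95% can arise by chance.

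In the miR-23/24/27 clusters 4 of 5 members were lower (median -0.18, 4.06 percentile, -0.27 with quantile normalization and 0.34 under the small RNA scaling). Here miR-27a and miR-27b stood apart from their cluster mates miR-23a (-0.01), miR-23b (0.003) and miR-24 (-0.18, or -0.27 with quantile normalization). In the miR-30 family 3 of 4 were lower, led by miR-30a (-0.37) and miR-30d (-0.22), with miR-30c at -0.10 and miR-30b at 0.04 (median -0.16, 7.41 percentile, 0.36 under the small RNA scaling). With quantile normalization the miR-30 median was -0.084, miR-30d was at -0.094 and miR-30b at -0.026, and with loess miR-30b was at -0.073.

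Liver-enriched miRNAs had 4 of 5 measured members lower, with a median of -0.13 at the 25.6 percentile, which became 0 with quantile normalization and 0.39 under the small RNA scaling. The members were miR-148a (-0.55), miR-378 (-0.47, or -0.30 with loess), miR-192 (-0.13), miR-194 (-0.09) and 1 above 0, with miR-192 at 0 and miR-194 at 0.073 under quantile normalization. miRNAs reported lower in liver cancer went both ways, with 3 of 8 higher and 5 lower. Their extremes were miR-214 and miR-125a-5p on the low side and miR-100 (0.51) and miR-99a (0.47) on the high side. That median of -0.10 lay at the 10.1 percentile, and it was 0.045 with quantile normalization and 0.42 under the small RNA scaling. The p53-responsive list had a median of -0.0003 and a mean of 0.16, at the 41.6 percentile, with miR-107 highest and miR-34a at 0.09 (0.021 with loess, 0.21 with quantile normalization). Its median was 0.14 with quantile normalization and -0.052 with loess. The miR-191 cluster list had a median of -0.05 (0.025 with loess, -0.017 with quantile normalization) at the 52.0 percentile, since only miR-191 among its 3 measured members was far from 0.

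**Figure D2:**
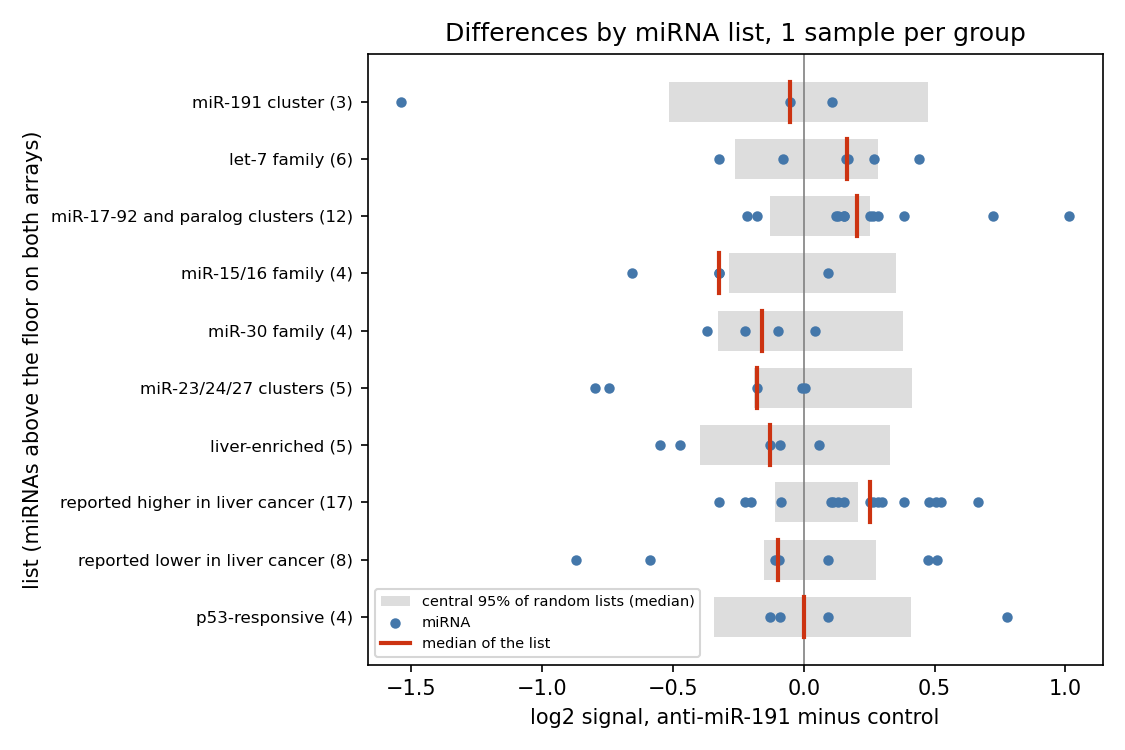
Log2 difference, anti-miR-191 minus control (x axis), of each measured miRNA (points) in the 10 lists with at least 3 members above the floor on both arrays, with the list median as a bar and the central 95% of random-list medians shaded. The medians of the miR-15/16 family (-0.32, or 0.20 when scaled to small RNA controls, which moves the shading equally) and of miRNAs reported higher in liver cancer (0.25) lie outside the shading.

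The remaining lists had too few measured members for a percentile. The miR-29 family had 1 of 3, miR-29a at -0.10 (-0.23 with quantile normalization, -0.19 with loess). The epithelial miR-200 family had 2 of 5, miR-200b at -0.56 and miR-200a at -0.07, which were -0.37 and -0.13 with quantile normalization, while miR-200a was -0.19 with loess. Of 36 C19MC miRNAs, a primate cluster active in placenta, miR-520a-3p alone was measured in both samples and 35 were at the floor in both. Of 40 miRNAs of the imprinted 14q32 cluster, miR-134 (-0.44, or -0.24 with loess) was measured in both samples and 38 were at the floor in both. No member of the cluster of miR-371, miR-372 and miR-373 was measured in both samples, and 1 of its 4 was above the floor in 1 sample.

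Markers of other cell types were mostly at the floor. Of 8 blood markers, 5 were at the floor in both samples, miR-146a was measured in both (-0.03) and 2 were above the floor in 1 sample, miR-223 among them. Of 11 endothelial, fibroblast and muscle markers, 9 were at the floor in both, and miR-214 and miR-126 were measured, the latter at -0.28, or 0.0073 with loess and -0.13 with quantile normalization. Of 8 neuronal markers, 6 were at the floor in both, and miR-128a (-0.22, or -0.11 with loess) and miR-128b (-0.22) were measured.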

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

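The miR-191 difference kept its direction and stayed beyond 2-fold under the 4 scalings that can move it (equal medians, quantile normalization, loess and small RNA controls). With small RNA controls it did so only narrowly (-1.02). The median used there is the value of 5s RNA (-0.52), and the 5 controls ranged from -0.76 to -0.19, so that margin depends on the control chosen. The other alternatives cannot change the miR-191 difference. No paired analysis was possible because each group has 1 sample. Setting medians equal, a floor at the 75th percentile and the brighter probe per name moved none of the 20 main results (counts, miR-191 and list medians); the last 2 also changed no measured miRNA, and values as deposited are the main values, so these 3 test nothing. At 1.5-fold, 5 miRNAs were higher and 8 lower; at 3-fold, 0 and 0. Without a floor, 3 were higher and 2 lower, because bounds then count, and medians over floored members were 0 for the let-7, miR-15/16, liver-enriched, miR-200, C19MC, 14q32, stromal and neuronal lists, and 0.13 for miRNAs reported higher in liver cancer. Quantile normalization gave list medians of -0.20 (miR-15/16), -0.23 (miR-29), 0 (liver-enriched), 0.045 (reported lower in liver cancer), 0.14 (p53-responsive) and 1.07 (C19MC). Loess gave 0.14 (reported higher in liver cancer), 1.13 (C19MC) and -0.24 (14q32); the cause of the moves under these 2 scalings was not tested. A floor at a log2 signal of 8, chosen after seeing the data, gave -0.72 (miR-191 cluster) and -0.87 (stromal), because low members dropped out. Scaling to small RNA controls, also chosen after seeing the data, adds 0.52 to every difference: miR-191 was then at -1.02, 9 miRNAs were at least 2-fold higher, and the miR-15/16 median reversed to 0.20, by that constant alone (its percentile among random lists stayed at 1.98). The other medians became 0.47 (miR-191 cluster), 0.69 (let-7), 0.72 (miR-17-92), 0.42 (miR-29), 0.36 (miR-30), 0.34 (miR-23/24/27), 0.39 (liver-enriched), 0.77 and 0.42 (reported higher and lower in liver cancer), 0.21 (miR-200), 0.52 (p53-responsive), 1.49 (C19MC), 0.079 (14q32), 0.49 (blood), -0.054 (stromal) and 0.30 (neuronal). Among the 54 other named differences, 21 moved with quantile normalization and 18 with loess. Signals near the floor of 50 limit what can be read from the 23 miRNAs measured in 1 sample only, and the list of miR-371, miR-372 and miR-373 gave no value.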

Other observations

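The tests in this part and their bounds were chosen after the result was seen. Only the loess and quantile normalization values and the miR-425 difference were planned, and not the bounds they were compared with. Several miRNAs whose genes share a locus differed unequally between the samples. In the miR-17-92 cluster the 9 other measured strands ranged from -0.22 (miR-92a) to 0.34 (miR-17*), against 1.01 for miR-17-5p. Of these, miR-92a and miR-19b (-0.18) also have a gene copy near that of miR-106a, so they do not report this locus alone. The star strand miR-92a-1* was at -0.04. miR-27b was at -0.80 while its own star strand miR-27b* was at -0.03 and miR-23b* of the same locus at -0.46, and miR-342 was at 0.54 while miR-342-5p was at -0.38. By contrast miR-27a (-0.74) and miR-27a* (-0.46) were both lower, and miR-192 (-0.13), miR-192* (-0.13) and miR-194 (-0.09), which share a locus, lay close together, as did miR-15b and miR-16. The miRNAs of this paragraph were picked by their values.

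The lower miR-191 signal is the pattern that the design names, since the anti-miR targets it. Lower output of the locus that reached both miRNAs alike would have lowered miR-425 too. The miR-425 difference was 0.11, above the bound of -0.77, which is the miR-191 difference divided by 2. The margin exceeded the SD of miRNA differences, a spread across miRNAs and not the error of a single difference. The miR-425 value argues against an equal lowering of both miRNAs in these 2 samples. Strands of other shared loci differed unequally here, so lower output that reached miR-425 less stays open. A trend of the difference with signal is argued against by the loess-corrected value of -1.55. It lay below the lowest uncorrected difference of the 40 miRNAs nearest in signal (-0.66) by more than their uncorrected SD (0.30). A dye effect on the miR-191 probe alone remains open, because 0 groups were measured in both dyes. Whether the anti-miR lowered the amount of miR-191 or kept it from being labelled or hybridised was not tested, and both may give a lower signal.

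The higher miR-17-5p, miR-106a and miR-107 are 3 of the brightest miRNAs and have close relatives on the array. More transcript of the miR-17-92 cluster would have raised its other strands. Their median was 0.15, from -0.22 to 0.34, against 1.01 for miR-17-5p. At the deposited scaling this argues against an equal rise of all strands as the cause for miR-17-5p, while a smaller rise stays open. The lowest strands, miR-92a and miR-19b (-0.18), also have a gene copy near that of miR-106a. The small RNA scaling adds 0.52 to these strands and to miR-17-5p alike. A trend over the bright range as the whole cause is argued against by the 8 other miRNAs with a mean log2 signal above 13. Their median difference was -0.0025, from -0.22 to 0.34, and 3 of them lie above 14, with a median of -0.09. Loess left miR-17-5p, miR-106a and miR-107 at 0.99, 0.70 and 0.75 (from 1.01, 0.72 and 0.78). Its span of 0.5 is too wide to follow a bend confined to the few brightest probes, so it decides nothing there. Quantile normalization lowered these 3 to 0.72, 0.22 and 0.46, and miR-103 from 0.34 to 0. A bend confined to the top of the signal range stays open. On the anti-miR-191 array miR-17-5p, miR-106a, miR-107 and miR-103 span 0.07 on the log2 scale, against 0.67 on the control array, a ratio of 0.103. An upper limit of the signal may have compressed them there, in which case the differences of miR-17-5p, miR-106a and miR-107 would be understated. On the control array miR-103 (15.04) was level with the brightest probe, 5s RNA (15.05), so a limit may have held there too. The highest signals of the 2 arrays differed by 0.35, close to the 0.34 of miR-103, whose difference may reflect only that. The miRNAs were chosen for this pattern and the point stays open, as do dye and cross-hybridisation between related sequences.

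A hypothesis was that related mature sequences differ alike whatever their locus, as miR-27a and miR-27b or miR-99a and miR-100 do. However, miR-99b of the latter family was at -0.12, against 0.47 for miR-99a and 0.51 for miR-100. The example pairs were seen first and are among the pairs tested. Over 52 pairs of family members from separate loci, the median gap between their differences was 0.28, against 0.32 for random reassignments, at the 24.8 percentile. Over 102 pairs from neighbouring genes and other families, with the strands of a single gene left out, it was 0.30 against 0.32, at the 34.2 percentile; a mature miRNA with several gene copies counted as a neighbour at any of them. The 35 pairs of strands from a single gene lay at the 9.85 percentile, and among miRNAs with a mean log2 signal of at least 8 the percentiles were 22.1 for 41 family pairs, 57.6 for 52 neighbouring pairs and 55.7 for 12 strand pairs. No set was closer than random pairs by the criterion of the 5th percentile. Over all pairs both explanations, by sequence and by shared transcription, stay open. Among the brighter miRNAs the neighbouring pairs had a median gap of 0.35 against 0.34 at random. These pairs include miR-191, the target of the anti-miR, with miR-425 (gap 1.65). They also include pairs of miR-17-5p and miR-106a, such as miR-17-5p with miR-92a (1.23), whose signals may be compressed. Such pairs may widen the gap for reasons other than transcription, so the comparison gives shared transcription no support there but cannot decide against it.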
